A study of Ovis aries with 6 samples.

How the data were processed

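Total RNA from body side and groin skin of 3 sheep was amplified, labelled with Cy3 and hybridised to single-colour Agilent sheep arrays, 1 array per sample, per the labels' protocols. The scanner intensity values were read by Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. The deposited processed signal is an intensity that Feature Extraction had corrected for background and for trends within the array, per the file headers; it was not normalized between arrays. The authors also deposited a table of log2 values for the same probes. All its columns have a median of 8.31, and each correlated at 0.999 with quantile-normalized log2 processed signals, so its scale is log2. Equal medians do not show that its arrays share 1 distribution, which was not checked. The offset from those signals (median absolute differences from 0.287 to 0.307) and the background step behind it are not given in the sources used here. Other columns used were the median spot and local background signals (intensity) and the spot flags. Scale and direction of the single-colour signals need no dye assignment.

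Samples were grouped by the body site in their titles, and replicate numbers were taken from the same titles. Replicates are separate animals. Number 1 is the ram at both sites; whether numbers 2 and 3 mark the same ewe at both sites is not stated. Deviations from the site means of same-numbered arrays correlated at 0.160 (the ram), 0.09 and -0.09 across probes, and those of groin 3 and body side 2 at 0.164. The known pair of the ram lay no higher than that, so the check cannot show which arrays pair. The numbers were not taken to pair the arrays in the main fit. Same-numbered pairs entered only the naming rule, counts of pairs, a block and the leave-outs given below. Of the 9279 called probes, 9190 had one direction in all 3 such pairs, so that demand removed few. The groin arrays had 1 scan and the body side arrays another, so no fit with the slide or scan as a term could be made.

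Control spots and spots with an outlier flag (between 6 and 51 per array among the non-control spots) were left out, and no non-control spot was saturated. The 50 probes with 5 spots were averaged on the log2 scale. The main values were log2 of the processed signal minus the 75th percentile of each array. A probe was tested where it was well above background on all 3 arrays of at least 1 site and had at least 2 values per site, which left 13278 probes and set aside 1730. Differences are body side minus groin, from limma 3.58.1 in R 4.3.3 with lmFit and eBayes, without a block, and with Benjamini-Hochberg adjustment (threshold 0.05). Standard errors are those of the moderated fit. Means are given with the SD of 3 arrays; the number of arrays limits their precision. The difference between the ram and the ewes was the interaction of site and sex in the same fit. A probe well above background on no array of a site was given a bound: the mean of the brighter site against the mean, over the arrays of the dimmer site, of the higher of the probe's own value and the lowest value of any probe well above background there. Such a bound holds only for the measured values with the main scaling. The differences of SCD, LEPR, AQP1 and VEGFA with normexp background correction, an alternative given below, fell short of theirs. Differences without scaling are those of the log2 processed signal itself.

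Probes were named through their RefSeq accession, without version, in a gene table of the sheep assembly ARS-UI_Ramb_v3.0; 734 probes matched and 14274 did not. The files name no genome build, so no coordinates are given. For a gene with several tested probes, the one with the highest mean over all arrays stands for it. Of the genes given with a difference in the text, 48 had another tested probe; for 6 the other probe had the opposite sign, and for 3 of these (ASIP, DGAT1 and ZFP36) both were called.

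Genes were named by a rule fixed, with the tests, the lists and most alternatives, before the data were examined. It takes the 10 largest rises and the 10 largest falls among named genes past the threshold with one direction in all 3 same-numbered pairs. From each of 30 gene lists for follicle, gland, muscle, vessel, fat, immune and other cell types and processes it takes up to 4 members past the threshold by smallest adjusted p, or else at most 1 with the smallest p, and it takes sex chromosome genes as a label check. A list entry was matched to current symbols, or to a synonym where no gene of the table holds that symbol. Lists with at least 3 tested genes were tested with limma camera against the other named genes. Genes named in the other observations and outside this rule were chosen after their values were seen.

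Alternatives were normexp background correction (offset 50), quantile normalization, median centring, the deposited log2 values, no filter on dim probes, a filter on all 6 arrays, a variance trend with robust estimation, a replicate block, array weights, the mean of all probes of a gene, each array and each animal left out, other thresholds, and camera with an estimated correlation or fry. An animal left out means both arrays of a replicate number, which are known to be of the same animal only for the ram. Normexp was run on the median spot signal with the local background median, since the deposited files hold no mean spot signal. Cyclic loess normalization and camera against all tested probes were added after the data were seen.

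The fits were tested on simulated arrays with the mean of each real probe and its spread pooled over both sites. Probes were drawn independently of each other, without a shift shared by an array, which real arrays can have. With 200 of 13278 probes changed between 3 and 3 arrays, 0% of the changes of 0.5 on the log2 scale were recovered, 48.0% of those of 1, 74.0% of those of 2 and 98.0% of those of 3, with 1 false call. For a simulated difference between the ram and the ewes, 4.00% of changes of 2 and 74.0% of changes of 5 were recovered. On simulated arrays of 442 named genes, camera called the inner root sheath list in 50 of 50 rounds when it alone was raised by 3, and a list in 3 of 50 rounds with no change. In the real arrays 314 of the 442 named genes and 9279 of the 13278 probes were called. The simulated rates hold for few changes among independent genes that are otherwise unchanged. They therefore do not tell how often camera, the probe fit or the fit of ram against ewes would find such changes, or call falsely, here.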

Results

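Gene expression in full-thickness skin of Aohan fine wool sheep was measured on 6 single-colour (Cy3) Agilent sheep arrays. The skin came from 3 animals of 12 months, 1 ram and 2 ewes that shared a father. The body side, which bears wool, gave 3 samples, and the groin, which does not, gave 3. The question behind the comparison, as far as the title of the series states it, was which genes go with wool in its growth phase. Each array held 15208 non-control spots. Between 10731 (body side replicate 1) and 14053 (groin replicate 3) probes were well above background. The groin arrays formed 1 scan and the body side arrays another, so that scan and body site cannot be told apart in any difference below. The 3 body side arrays were dimmer: the 75th percentile of the processed signal was 2.98 times as high on the groin arrays, with a difference of -1.57 on the log2 scale (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays allow). Levels are therefore given as log2 signal minus the 75th percentile of the array. A gene symbol was found for 734 probes, for 476 genes of which 442 were tested, and 14274 probes had none.

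Genes of the wool fibre and of the sheath around it were higher on the body side. KRTAP5.4, a keratin-associated protein of the fibre matrix, was 31.7-fold higher (log2 difference 4.99 ± 0.29 SE, limma adjusted p = 9.94e-06), at 6.28 ± 0.46 on the body side against 1.29 ± 0.40 in the groin (SD, n = 3 each). KRT35, a hair shaft keratin, was 26.4-fold higher, at 7.13 ± 0.39 against 2.41 ± 0.18. Among the genes that were lower there, ACLY, which makes cytosolic acetyl-CoA, was 11.8-fold higher in the groin. SCD, the stearoyl-CoA desaturase, was at least 24.9-fold higher in the groin with the main scaling, and its log2 difference was -2.52 with normexp background correction. Of the 442 named genes, 201 rose on the body side, 113 fell and 128 did not pass the threshold.

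The 10 largest rises among named genes held 6 genes of the follicle's keratin programme. Besides KRTAP5.4 and KRT35 these were K38, a wool keratin (log2 difference 3.40 ± 0.24 SE), V15, which the gene table also lists as KRT31 (3.36 ± 0.17), KRT27 of the inner root sheath (3.31 ± 0.27) and KRTAP4.3 (2.94 ± 0.22). The other 4 were SFTPC, a surfactant protein of the lung (3.37 ± 0.19), CRYAB, a small heat shock protein (3.25 ± 0.21), CYP17A1, an enzyme of steroid synthesis (2.78 ± 0.22), and LGALS15, a galectin (2.77 ± 0.25). Without scaling between arrays, the differences of these 10 genes ran from 1.19 for LGALS15 to 3.41 for KRTAP5.4, all still above 0 although the body side arrays were dimmer. With cyclic loess KRTAP5.4 was at 3.92, KRT35 at 3.44, V15 at 2.08, KRT27 at 1.75 and CRYAB at 2.02, and CYP17A1 was at 1.84 with the mean of its probes. The highest limma adjusted p among the 10 was 6.23e-05.

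Among the 10 largest falls, CA1, a carbonic anhydrase, had a measured log2 difference of -7.06 ± 0.22 SE, but only 1 of the 3 body side arrays read its probe well above background, and its other probe gave -4.48 ± 0.29. SCD was below that mark on all 3 body side arrays and has only the bound given above; its measured means were -7.50 on the body side and -1.42 in the groin. CYP1A1, an oxidase of foreign compounds, differed by -4.82 ± 0.29, from 1.37 ± 0.49 in the groin to -3.44 on the body side. RASSF1 differed by -4.21 ± 0.49 with 1 body side array well above background, FHL1 by -3.88 ± 0.24, and MMP2, a gelatinase of the dermis, by -3.71 ± 0.20 with 2 such arrays. TRPM7, a channel with a kinase domain, differed by -3.58 ± 0.34 with 2 such arrays, ACLY by -3.56 ± 0.17, IGFBP3, a carrier of insulin-like growth factors, by -3.36 ± 0.37 with 1 such array, and ARFIP2 by -3.34 ± 0.28. With normexp the differences were smaller, at -4.75 for CA1, -1.39 for RASSF1, -2.57 for FHL1, -1.72 for TRPM7, -0.95 for IGFBP3 and -2.06 for ARFIP2, all past the threshold. The highest limma adjusted p among the 10 was 1.76e-04.

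**Figure D1:**
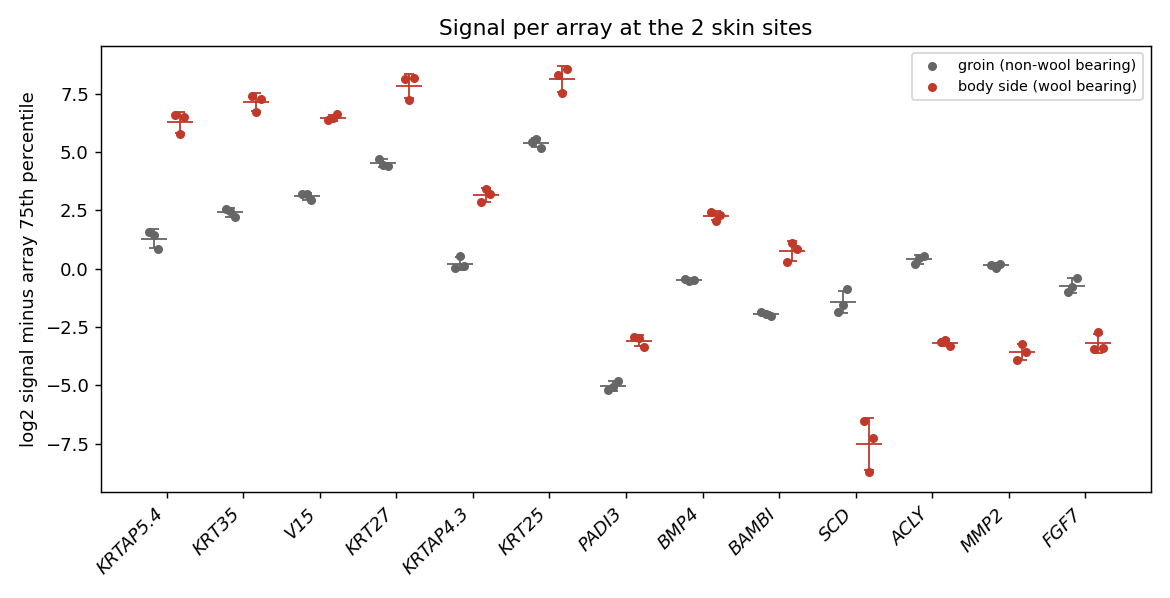
Each point is 1 array, for 13 genes along the horizontal axis, with log2 signal minus the 75th percentile of the array on the vertical axis; horizontal marks and bars are the mean and SD of the 3 arrays of a site. The keratin genes, BMP4 and BAMBI lie higher on the body side (red) with no overlap, and SCD, ACLY, MMP2 and FGF7 lie lower; SCD on the body side was not well above background.

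In the fixed gene lists, all tested members of the 3 lists for the wool fibre and its sheath rose. Both genes matched to the hair shaft keratin list (KRT35 and V15) rose, and so did both keratin-associated proteins (KRTAP5.4 and KRTAP4.3). K38, the wool keratin named above, was matched to no list entry and is not counted in these lists. The inner root sheath list had 3 tested members, which all rose: KRT27, KRT25 (2.74 ± 0.28 SE, 6.66-fold) and PADI3, a peptidylarginine deiminase that modifies structural proteins of the hair (1.94 ± 0.20, 3.85-fold). All 7 genes of these lists kept their call under every alternative run; KRT25, at 1.06 with cyclic loess, moved most in proportion. Without scaling between arrays PADI3 differed by 0.37 and KRT25 by 1.16. KRT25 and KRT27 were also bright in the groin, at 5.39 ± 0.19 and 4.52 ± 0.17 (SD, n = 3). No gene of the lists for matrix and cortex regulators, epidermal differentiation, basal keratinocytes or nerve had a named probe.

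The signalling list and the dermal papilla list each held genes that rose and genes that fell. Of 5 tested members of the Wnt, hedgehog, BMP, FGF and Notch list, 3 rose, 1 fell and FGF2 did not pass. BMP4, a secreted ligand, was 6.72-fold higher (2.75 ± 0.17 SE, limma adjusted p = 1.16e-05). BAMBI, a decoy receptor of the same pathway, was 6.43-fold higher (2.68 ± 0.23) and the receptor BMPR1B 3.39-fold higher (1.76 ± 0.21). Without scaling between arrays the differences were 1.17 for BMP4, 1.11 for BAMBI and 0.19 for BMPR1B. TGFB1 fell by 1.09 ± 0.18. Of the 5 dermal papilla genes, FGF7 fell by 2.46 ± 0.25. With the main scaling the brightest probe of LEPR, the leptin receptor, was at least 3.44-fold higher in the groin. That probe was well above background on no body side array (measured means -7.38 and -4.27). The other LEPR probes differed by -2.31 ± 0.52 and by -0.67 ± 0.30, the latter not past the threshold. The call on the brightest probe ended with normexp, at -0.36 with an adjusted p of 0.264 in a range over all alternatives from 1.08e-06 to 0.264. IGF1 rose by 0.66 ± 0.20, a call that ended without replicate 3 (0.56, adjusted p = 0.163) and in 3 other leave-outs, and FGF10 and NOG did not pass. IGFBP5, the 1 tested gene of the follicle stem cell and outer root sheath list, fell by 1.44 ± 0.20 (-0.87 with normexp).

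Glands and fat gave mixed lists. Of 7 sebaceous gland and lipid synthesis genes, 2 fell (SCD and ACLY), 2 rose and 3 did not pass; the median log2 difference was 0.12 and the mean -1.18. ACACA, the carboxylase that commits acetyl-CoA to fatty acids, rose by 0.77 ± 0.18 SE (adjusted p = 0.0596 without replicate 3). DGAT1, which completes triglycerides, rose by 0.46 ± 0.16, but its other probe was called the opposite way, at -0.83 ± 0.19, and the mean of both probes was -0.18. Of 4 adipocyte genes, LPL fell by 0.71 ± 0.18, with 1 body side array well above background, and was at 0.51 and not past the threshold with normexp; PLIN1 rose by 0.62 ± 0.23, but its other probe did not pass (0.085 ± 0.21). The call on LPL also ended without replicate 3 (-0.53), that on DGAT1 without replicate 3 (0.50) and that on PLIN1 without replicate 1 (0.35) and with quantile normalization (0.13). SQLE, the 1 cholesterol synthesis gene tested, rose by 0.89 ± 0.26, but was lower by quantile normalization (-0.46), with the series values (-0.49) and with cyclic loess (-0.47), and its call ended without replicate 3 (0.68); its other probe did not pass (0.44 ± 0.23). Of 3 sweat gland genes, 2 rose, AQP5, a water channel of secretory cells, by 2.11 ± 0.38 (its other probe did not pass, at 1.11 ± 0.53) and CFTR by 0.62 ± 0.23, with 1 body side array well above background and the call ended without replicate 1 (0.51). Of 5 milk protein genes, CSN3 rose by 1.38 ± 0.20 (-0.19 without scaling between arrays) and 4 did not pass. Among these 4, the dimmer LALBA probe was called higher.

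Immune cell genes also moved both ways. Of 12 myeloid genes, 5 rose, 3 fell and 4 did not pass by the brightest probe of each. Among those 4, the dimmer probes of CD14 and TLR2 were called lower. CXCL8, a neutrophil attractant, rose by 2.47 ± 0.20 SE and TNF by 1.60 ± 0.18, whereas IL1A fell by 2.11 ± 0.23 and TLR4, the receptor for bacterial lipopolysaccharide, by 1.52 ± 0.18 (-0.93 with normexp). The median of that list was -0.02 and the mean 0.12. Of 5 T and NK lymphocyte genes, 3 rose, 1 fell and 1 did not pass. CD3E rose by 1.63 ± 0.17 (1.05 with cyclic loess), CD3D by 1.36 ± 0.19 and CTLA4 by 0.60 ± 0.22 (0.54 and not past the threshold without replicate 3), and CD247, another chain of the same receptor complex as CD3E and CD3D, fell by 1.18 ± 0.22 (-0.55 with normexp). CR2 of the B cell list fell by 1.68 ± 0.18. Of 3 mast cell genes, the tryptase TPSB2 fell by 1.27 ± 0.18 and FCER1A rose by 0.44 ± 0.16, with its other probe at -0.59, the mean of both at -0.075, and the call ended without replicate 3 (0.42). Without scaling between arrays, TNF differed by 0.030, CD3E by 0.051 and CD3D by -0.21.

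Of 3 dermal fibroblast genes, MMP2 fell, BGN, a small proteoglycan, fell by 0.86 ± 0.19 SE, and DCN, another small proteoglycan, rose by 0.89 ± 0.24. The sign of DCN turned with quantile normalization (-0.36), the series values (-0.37) and cyclic loess (-0.81), and its other probe did not pass (0.32 ± 0.18). The calls on DCN and BGN ended without replicate 3 (0.69 and -0.69), and that on BGN also with median centring (-0.40). Both tested endothelial selectins fell, with SELE 2.82-fold higher in the groin (log2 difference -0.78 with normexp) and SELP at -0.69 ± 0.16; the call on SELP ended with normexp (-0.042), quantile normalization (-0.30) and median centring (-0.24), and without replicate 3 (-0.71). In the red blood cell list, CA1 fell and the globin HBB rose by 1.70 ± 0.43. Both tested pigment genes rose, TYR, the tyrosinase of melanin synthesis, by 1.79 ± 0.20 and ASIP, the agouti signal, by 1.79 ± 0.24; a second ASIP probe was called the opposite way, at -0.85 ± 0.19, and the brighter probe was at 0.50 with cyclic loess and 0.52 with quantile normalization. Of 4 skeletal muscle genes, 2 rose, MB by 1.86 ± 0.31 (its other probe did not pass, at 1.04 ± 0.48) and MYL11 by 1.01 ± 0.20, and 1 fell, TNNC2, by 0.71 ± 0.24, with 2 body side arrays well above background; TNNC2 was at 0.33 and not past the threshold with normexp, and its call ended without replicate 3 (-0.71). With quantile normalization MYL11 (0.21) was no longer past the threshold. Without scaling between arrays, TYR differed by 0.22, ASIP by 0.21, MB by 0.28, HBB by 0.13, MYL11 by -0.56 and DCN by -0.68. CNN1 of smooth muscle (-0.35 ± 0.23, adjusted p = 0.194) and HOXC6 of the body position list (-0.37 ± 0.21, adjusted p = 0.147) did not pass; both were above 0 with median centring, and both passed with quantile normalization, at -1.57 and -1.20.

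Among the immediate early genes, EGR1 rose by 1.40 ± 0.19 SE and ZFP36 by 1.19 ± 0.18, and FOS fell by 2.89 ± 0.34 (-1.15 with normexp), with 1 body side array well above background, and MYC by 0.84 ± 0.27. The call on MYC, which lacked 1 value and did not enter camera, ended without replicate 1 (-0.39), and its other probe did not pass (-0.25 ± 0.18). A second ZFP36 probe was called the opposite way, at -3.32 ± 0.34, the mean of both was -1.06, and the brighter probe was at 0.58 with cyclic loess. CDK1 of the cell cycle list rose by 1.56 ± 0.17, and AURKA did not pass. Without scaling between arrays, CDK1 differed by -0.010, EGR1 by -0.18 and the brighter ZFP36 probe by -0.38. Of 4 ribosomal protein genes, RPL10 (1.32 ± 0.23), RPS26 (1.05 ± 0.22) and RPS25 (1.02 ± 0.39) rose. With cyclic loess these 3 were below 0, at -0.38, -0.63 and -0.66, but only RPS26 passed the threshold there. RPS26 (-0.25) and RPS25 (-0.23) were below 0 with quantile normalization too, where neither passed. The call on RPS25, higher in 2 of 3 same-numbered pairs, ended without replicate 3 (0.50), as did that on RPS26 (0.87). Of 4 oxidative phosphorylation genes, NDUFA12 (1.26 ± 0.21), ATP5MC2 (1.38 ± 0.23) and ATP5PO (1.40 ± 0.31) rose; none of the 3 passed with quantile normalization, where ATP5MC2 turned to -0.04. These genes lie among the brightest probes, and the site difference moved with brightness: in 10 equal groups of tested probes by signal its median was 1.13 in the brightest and -0.42 in the fifth.

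**Figure D2:**
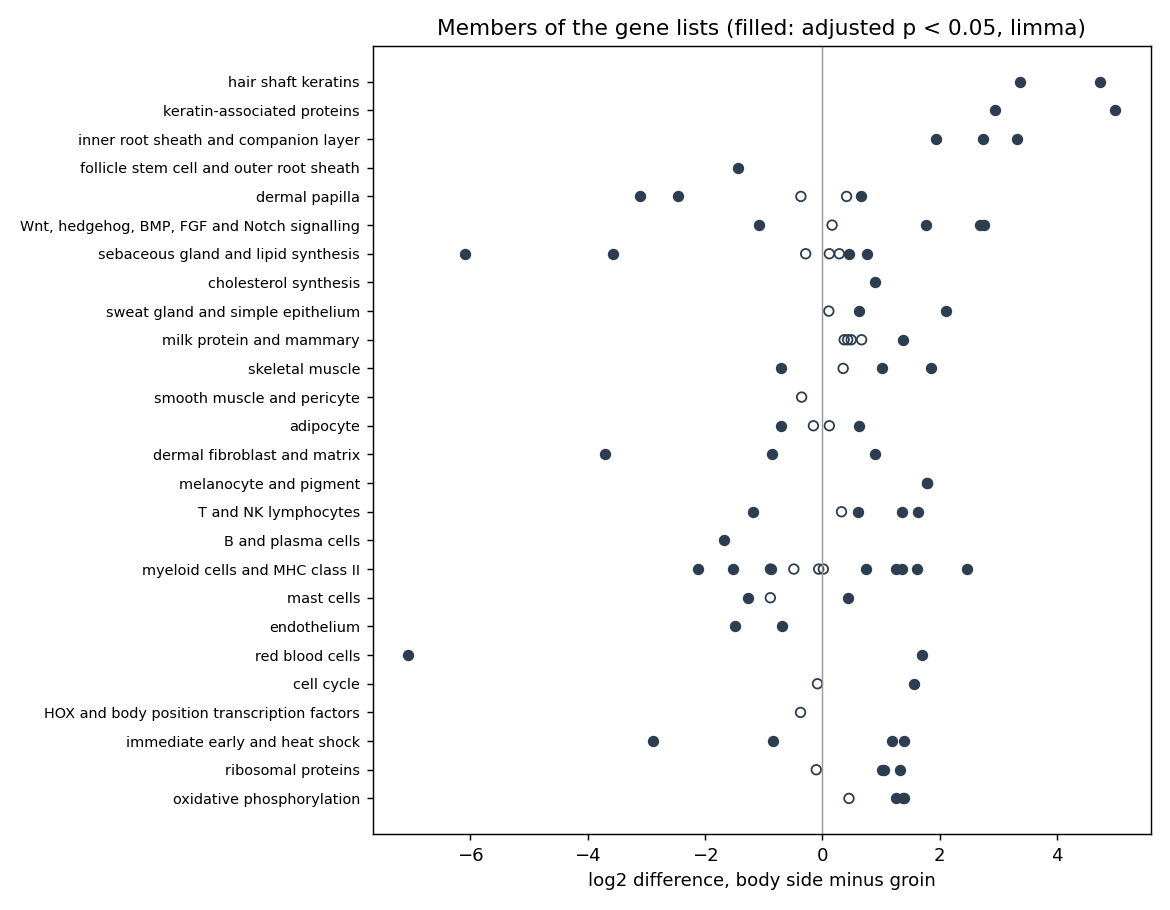
Each circle is 1 tested gene, placed by its log2 difference (body side minus groin, horizontal axis) in the row of its list; filled circles passed the limma threshold of 0.05. The hair shaft, keratin-associated and inner root sheath rows lie wholly above 0, between 1.94 and 4.99, and several other rows hold members on both sides; SCD at -6.08 and LEPR at -3.11 are drawn at measured values, not at their bounds.

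Over all 13278 tested probes, limma called 9279 (69.9%) at an adjusted p under 0.05, 4918 higher and 4361 lower on the body side, of which 5947 also differed at least 2-fold. Higher calls made up 53.0% of the total, but 68.5% with median centring and 68.6% with normexp, settings that raise the median difference of all tested probes by 0.46 and 0.36. With a filter on all 6 arrays they made up 61.8%, with 4801 higher and 2963 lower calls. The count of lower calls thus depended more than that of higher calls on probes not well above background on every array. Among the probes without a gene symbol, the largest differences were those of A_70_P060621 at 6.72 ± 0.23 SE and A_70_P006991 at -6.60 ± 0.26, the latter well above background on 1 body side array. The groups did not overlap for 74.8% of the tested probes, where chance gives 10%. Correlations between arrays of a site lay between 0.979 and 0.993 across probes, which are not independent replicates, and between sites from 0.878 to 0.930.

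**Figure D3:**
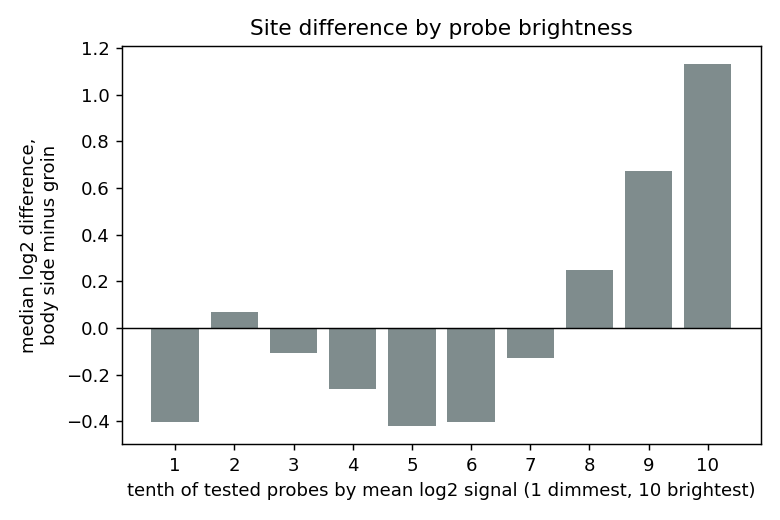
Bars give the median log2 difference (body side minus groin, vertical axis) of the tested probes in 10 equal groups of mean log2 signal (horizontal axis, dimmest to brightest). The medians lie at -0.42 in the fifth group and rise to 0.67 and 1.13 in the brightest 2.

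Tested as sets against the other named genes, none of the 15 lists with at least 3 tested genes passed (limma camera, preset correlation 0.01). The adjusted p ran from 0.412, for the inner root sheath list, to 0.791, and before adjustment 1 list was under 0.05. With an estimated correlation, the adjusted p lay between 0.647 and 0.856. The directional test fry, which does not compare a list with other genes, called 12 lists, 8 higher and 4 lower, among them the inner root sheath list (adjusted p = 4.28e-04) and the signalling list (1.36e-05) as higher and the dermal fibroblast list (2.33e-04) as lower. For the myeloid list camera pointed down and fry up, and for the immediate early list camera pointed up at a median of 0.17 and a mean of -0.29. For the sebaceous list camera pointed down against a median above 0. Adjusted over the list alone, the counts of members that rose or fell were those given above except that PLIN1 was lost from the adipocyte list, the mast cell list gained another fall and the oxidative phosphorylation list another rise.

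The site difference could also be compared between the ram and the ewes, since each sex was sampled at both sites. It differed for 15 probes (limma interaction term, adjusted p under 0.05), with the ram's difference above that of the ewes for 4 and below it for 11. None of the 15 carried a gene symbol. The largest was A_70_P043041, at 4.44 in the ram against -1.02 in the ewes, and the most negative A_70_P031976, at -5.27 against -0.93. The ram gave 1 array per site, assumed to vary like those of the ewes, so that sex cannot be told apart from this animal or from its body side array, the dimmest of the 6. The count moved with the processing, from 0 with normexp or with no filter on dim probes to 243 with a block on the replicate number. No gene of the sex chromosome list had a named probe, so the sex labels could not be checked.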

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

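The tests of the slides, of brightness, of random sets of probes and of other splits of the arrays were chosen after the results they bear on were seen. The site difference differed between the ram and the ewes for 15 probes by the interaction term, in which the spread comes from the 2 ewes alone. With replicate 2 or replicate 3 set as the odd animal in place of the ram, the ram's arrays enter the spread, so any deviation of the ram widens it. These numbers are also not known to mark the same ewe at both sites. Such fits are therefore no control for the difference of the ram.

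Between the sites 9279 of 13278 probes were called. The bright corner control spots, which hold no sheep RNA, were dimmer on the body side arrays by -1.63 on the log2 scale, about as much as the 75th percentile of the sheep probes (-1.57). A shift that depends only on signal cannot account for most calls, since cyclic loess, which removes it, called 8742 probes, and 7548 of the 9279 were called in the same direction. Of the 10 splits of the 6 arrays into 3 and 3, only the real split (1 of 10) gave 9279 probes, and the highest of the others gave 0; 10 splits are too few for a share under 0.05. For the lists, camera called 0, so that all splits (10 of 10, highest other 0) give as many whatever their values, and the count bears on nothing. How much of the count comes from the slides or scans and how much from body site cannot be told apart, because each scan holds 1 site.

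The rise of the 7 wool fibre and sheath genes was weighed against the same technical differences. After cyclic loess the lowest of the 7 was KRT25 at 1.06, and all 7 stayed above 0, which argues against the shift with brightness as the whole cause. Their median difference, 3.31, lay at percentile 100 of 10000 random sets of 7 probes of like signal, but the 3 lists were singled out because all their members rose, so that this decides nothing. When each draw instead filled all 26 lists with random probes and pooled the 3 lists with the highest medians, the 7 genes lay at percentile 98.7, short of the bound of 99 set beforehand. Only 15 lists held at least 3 tested genes, so a draw could pool fewer than 7 probes. The random probes also carry any true difference between the sites. This percentile therefore cannot weigh a slide difference either. A slide difference that falls on probes irrespective of gene stays open, as do one that falls on particular sequences, which no value here tests, and the hypothesis that wool-bearing skin holds more of these transcripts.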

How the results depend on the processing

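Cyclic loess and camera against all tested probes were chosen after the data were seen; the other settings were planned. The count of probes changed stayed within 1.5 times of 9279 under every normalization, filter, variance model and weighting tried, from 7764 with a filter on all 6 arrays to 11333 with array weights, whose estimate stopped before it settled and gave 1 body side array a weight of 19.4. It was 5947 with a 2-fold minimum, which removes small differences. With unadjusted p and that minimum it was 5963, and with a plain equal-variance test, unadjusted p and that minimum 5753. These last settings change more than 1 choice at once. Leaving out arrays or animals gave 6564 to 9746 probes. With the replicate number as a block it was 9211, and no list was called. Slide or scan as a block was not run, as each scan holds 1 site. The interaction count of 15 was 0 with normexp, 6 with median centring, 5 with the series values, 0 with no filter on dim probes, 177 with a variance trend, 243 with the replicate block and 4 with cyclic loess; the cause was not tested. Camera called 0 lists throughout, 0 to 0 with arrays or animals left out, and fry called 12, since it does not compare a list with other genes.

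Named genes kept direction and side of the threshold in 1420 values, lost the call in 105, gained one in 25 and turned in 32. Leaving out an array or an animal (9 ways) ended the call on 16 named genes: in 7 ways each for CFTR, DGAT1, FCER1A, PLIN1 and RPS25, in 6 for CTLA4 and MYC, in 5 for TNNC2, in 4 for IGF1, in 3 for SQLE, and only without replicate 3 for ACACA, BGN, DCN, LPL, RPS26 and SELP. Those that turned are given next; the cause was not tested. With quantile normalization ATP5MC2 was at -0.045, DCN -0.36, RPS25 -0.23, RPS26 -0.25 and SQLE -0.46. With the series values ATP5MC2 was at -0.040, DCN -0.37, RPS25 -0.22, RPS26 -0.25 and SQLE -0.49. With cyclic loess ATP5MC2 was at -0.15, DCN -0.81, RPL10 -0.38, RPS25 -0.66, RPS26 -0.63, SQLE -0.47 and CYP11A1 -0.051. With median centring CNN1 was at 0.10, HOXC6 at 0.085, IGF2 at 0.25 and IGFBP2 at 0.37, with array weights IGFBP2 at 0.035, and with normexp LPL at 0.51, TNNC2 at 0.33, VEGFA at 0.15 and CP at 1.11. With arrays or animals left out, CYP11A1 ran from -0.32 to 0.97. With the mean of all probes DGAT1 was at -0.18, FCER1A -0.075 and ZFP36 -1.06, since their probes disagree.

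No list passed in camera, so the lists that turned have no call to lose. Their adjusted p was 0.775 for the adipocyte list with normexp. For the myeloid list it was 0.721 with quantile normalization, 0.727 with the series values, 0.681 with cyclic loess, 0.217 with fry and 0.860 against all tested probes. For the immediate early list it was 0.727 with the series values, 0.328 with the mean of all probes, 0.747 without body side replicate 3, 0.908 without replicate 1 and 0.728 without replicate 3, where its direction turned, in a range of 0.723 to 0.962 over all leave-outs. For the ribosomal list it was 0.521 with quantile normalization, 0.528 with the series values and 0.385 with cyclic loess, and for oxidative phosphorylation 0.625, 0.647 and 0.672 in that order. Probes near background limit the rest: the share well above background was 71.5% on body side replicate 1 and 93.6% on groin replicate 3.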

Other observations

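The gene groups below and the list of genes of other organs were chosen after the values were seen, as were all tests in this part except the slope within groups and the control probes. Of 6 tested genes of the insulin-like growth factor family, 3 fell, IGFBP3, IGFBP5 and IGFBP1 (-1.35 ± 0.18 SE, limma adjusted p = 3.10e-04, lower in 3 of 3 same-numbered pairs), 1 rose (IGF1), and the brighter probes of IGF2 (-0.20) and IGFBP2 (-0.091) did not pass. The dimmer IGF2 probe was lower, at -2.52 (adjusted p = 4.29e-05), and with cyclic loess the brighter probes were at -1.07 and -1.30, both past the threshold, but above 0 with median centring. With normexp the call on IGFBP1 ended, at -0.16. Of 4 cathelicidins, which are antimicrobial peptides, 3 rose and 0 fell, with a median of 1.13 that was -0.44 without scaling. Those that rose included BAC5 and CATHL1B, each well above background on only 2 body side arrays, and CATHL3 did not pass. Of 11 interleukins 6 rose and 4 fell. Of 6 genes of lipid droplets and lipid desaturation (ABHD5, PLIN1, PLIN2, PLIN5 and the desaturases SCD and SCD5) 3 rose and 2 fell, SCD among the latter. Of 6 matrix metalloproteinases and their inhibitors 2 rose and 3 fell, of 8 Toll-like receptors 2 rose and 2 fell, and of 9 mitochondrial carriers 0 rose and 3 fell. These counts took the brightest probe of each gene, and the dimmer TLR2 probe was called lower. None of these families was tested as a set. AQP1, a water channel of capillaries, was at least 4.38-fold higher in the groin with the main scaling. Its brightest probe was not well above background on the body side (measured means -6.83 and -3.93). VEGFA, a growth factor of vessels, was likewise at least 1.96-fold higher in the groin with that scaling. With normexp the call on AQP1 ended, at -0.54, and VEGFA turned to 0.15. That setting adds an offset of 50, which raises dim signals most on the log2 scale. With the main scaling the other probes of both genes were also lower on the body side and past the threshold, at -3.54 ± 0.27 for AQP1 and -2.86 ± 0.30 for VEGFA.

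A list of genes known for expression in pituitary, placenta, gonad, gut, liver, lung and other organs, SFTPC among them, had 31 tested members, of which 25 rose and 1 fell, with a median of 1.28; of all 442 named genes 201 rose. With cyclic loess 24 of the 31 rose. The list is not complete: ALB (-0.53 ± 0.30 SE), CP (-0.68 ± 0.36) and CYP11A1 (0.27 ± 0.41), of the same kinds of organ, are not on it and did not pass. These values turn with the processing: with normexp CP was at 1.11 and CYP11A1 at 1.16, both past the threshold, with cyclic loess CYP11A1 was at -0.051, and ALB passed with array weights (-0.45). A candidate explanation is signal that does not follow the amount of labelled RNA and is raised by the scaling. Without scaling their median difference was -0.29, against -1.47 over all tested probes, but scaled and unscaled values differ by a constant, so this follows from the choice of genes; the 10 E1A control probes had a median of -0.072, which rests on probes near background. The 3 of them that were well above background on most arrays were lower on the body side, at -1.03, -0.68 and -0.55, which is a smaller fall than that of all tested probes but no lack of response. Within the sites, where the brightness of the arrays also differs, the signal of these genes moved with the 75th percentile of the array at a median slope of 0.55 (quartiles 0.46 and 0.78), between no response and the 0.99 of other probes of like signal. The groin arrays differed little in that percentile (SD 0.13 on the log2 scale). The slope rests mainly on body side replicate 2, at 2048 against 1103 and 1130.5 on the other body side arrays. The explanation stays open, as does a true difference in the skin.

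Pairs of probes for one accession, both well above background on all 6 arrays, gave 342 comparisons within a transcript. Their differences correlated at 0.862 across pairs. In 43 pairs the brighter probe was higher on the body side and the dimmer one lower, and in 4 pairs the reverse held; where both probes were called, the numbers were 13 and 1. After cyclic loess the numbers were 27 and 13 over all pairs, and 10 and 6 where both probes were called. The named genes among the 13 were ACVR2A, ASIP, CYB561, DGAT1, EDNRA and YBX1.

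The ram was apart from the other arrays of the site by over 1 on the log2 scale, in the same way at both sites, for 6 of 13278 probes. For the other pairings of 1 groin array with 1 body side array, which are not known to share an animal or do not, the count ran from 0 to 14, the latter for groin replicate 3 with body side replicate 1.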
